A study of Mus musculus with 5 samples.

How the data were processed

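Chromatin immunoprecipitation and sequencing (ChIP-seq) for histone H2A ubiquitinated at lysine 119 (H2AK119Ub) was done on lineage-negative haematopoietic progenitors of C57BL/6 mice, per the labels' protocols. The mark is deposited by Polycomb repressive complex 1 (PRC1), whose catalytic subunits are RING1A and RING1B. The cells were fixed with 1% formaldehyde and their chromatin was sheared to 200 to 300 bp on average before immunoprecipitation. 5 samples were described: 4 immunoprecipitated libraries and 1 input. A peak list was analysed for each of the 4 immunoprecipitated libraries, and the input was not analysed here.

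Peaks were called by the authors for each library. Per the submitters' processing notes the tools were Bowtie and MACS2 and the genome build was mm9; versions, parameters and the use of the input are not given in the sources used here. Each deposited file was a peak list with 5 columns and no header (chromosome, start, end, peak name and score). The deposited score of each peak is the authors' own value; its scale is not stated, and it was used only to describe, rank or filter peaks within their own list, apart from 1 ratio of scores between lists in the closing observations, which was read as deciding nothing. The deposited start and end positions were read as BED positions and are printed counting from 1. The lowest score of any deposited list was 700, and the numbers in the peak names had gaps, so the deposited lists hold a part of the numbered peaks. A filter on the score is one reading of these gaps; peaks left out for other reasons would look the same. In every list the peak numbers ran in order along the chromosomes. No list held peaks that overlapped each other. Because the lists hold no read counts, the depth of the libraries is unknown and no interval that needs it is given.

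Each group had 1 library, so no test between groups was possible and no p-value is given. Differences between lists compare these libraries, not the conditions, and peak number depends on sequencing depth and on the yield of the immunoprecipitation as well as on the mark. Shares of peaks are given with exact (Clopper-Pearson) 95% binomial intervals, and medians of ratios and ratios of medians with 95% intervals from 2000 bootstrap resamples. These intervals treat peaks as independent and cover counting error only.

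Peaks of 2 lists were called overlapping when they shared at least 1 bp. For comparison, the peaks of the second list were placed at random 1000 times, each on its own chromosome, within the span that peaks of any list covered. Peaks of all 4 lists were then merged into regions where they overlapped or touched, and each region was assigned to the libraries with a peak in it; a merged region can therefore join peaks of 2 libraries that are linked only through a peak of another library. One-to-one pairs were peaks of 2 lists that overlapped each other and no other peak of the 2 lists. The missing peak numbers were used to ask where an unlisted call could lie: where no number was missing between the listed peaks on both sides of a position, no call of that library was left out there.

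Regions were named by a rule fixed before the data were examined: up to 5 regions per rule, by score rank, among regions of all 4 libraries, those with the highest score in each library, those in all 3 oncogene libraries but not in the non-transduced one, and those in 1 library alone. Genes were not assigned to peaks. The gene table at hand belongs to a later mouse assembly than mm9, and an mm9 annotation was not used here, so the planned counts of promoters and of gene groups were left out and all results are given by mm9 position. Alternatives fixed beforehand were stricter lists (the upper 75% or 50% of each list by score), the best 620 peaks of each list, an overlap of at least 50% of the peak, a distance of up to 1000 bp, and merging of peaks within 1000 bp. Leaving out the HOXA9 library and random placements that keep the spacing of a list or move each peak by up to 1 Mb were added after seeing the data, as were expected numbers of shared regions within classes of like score or of like score and covered length.

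The interval code was tested on simulated data before use. Of 700 simulated shared peaks 700 were found, and for 20 of 20 simulated pairs of independent lists the observed overlap lay within the central range of the random placements. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.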

Results

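H2AK119Ub was mapped by ChIP-seq in lineage-negative bone marrow progenitors that carried a Cdkn2a deletion, a Ring1a deletion and conditional Ring1b alleles; whether these had been deleted is not stated in the labels. Cdkn2a encodes the tumour suppressors p16INK4A and p19ARF, and the Ring1 genes encode the ubiquitin ligases of PRC1. One culture was left non-transduced, and the others were transduced with the homeobox gene HOXA9, with the fusion oncogene PML-RARa of acute promyelocytic leukaemia, or with the fusion oncogene MLL-AF9 of acute myeloid leukaemia. There was 1 library per group and 4 peak lists in all, with 5132 peaks together. The question was how the distribution of the PRC1 mark in progenitors transduced with each oncogene compared with that in non-transduced progenitors. No group had replicates, so every difference below is a difference between single libraries. No library of cells transduced without an oncogene was described, so effects of an oncogene and of transduction cannot be told apart.

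H2AK119Ub peaks were broad in all 4 libraries, with median widths from 14.6 to 18.3 kb and single peaks of up to 174 kb. The PML-RARa library had the longest list, with 1772 peaks over 35.7 Mb, and the HOXA9 library the shortest, with 620 peaks over 13.4 Mb. The non-transduced library had 1332 peaks over 31.4 Mb. The MLL-AF9 library had more listed peaks than the non-transduced one (1408) but a smaller covered length (27.0 Mb). Its peaks were also narrower, with a median of 14.6 kb against 18.3 kb. Relative to the non-transduced list, the covered length was 0.426 in HOXA9, 1.14 in PML-RARa and 0.859 in MLL-AF9. The depth of all 4 libraries was unknown.

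**Figure D1:**
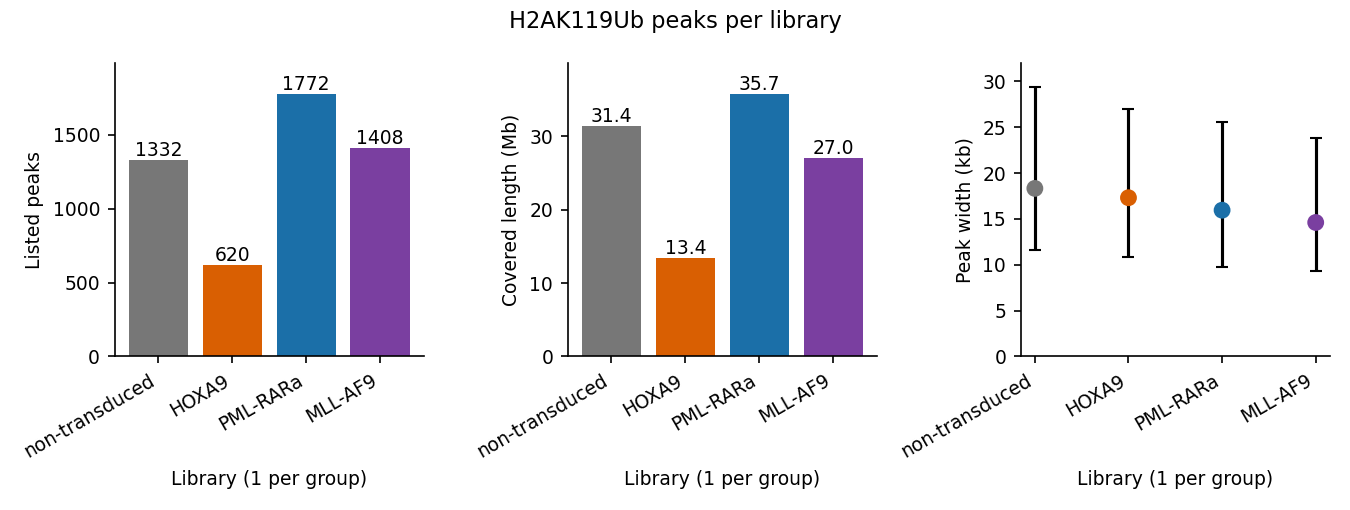
Number of listed H2AK119Ub peaks, their covered length in Mb and their width in kb (point, median; bars, quartiles) in each of the 4 libraries, with 1 library per group. The HOXA9 list is the shortest on both counts (620 peaks, 13.4 Mb), and the MLL-AF9 list has the lowest median width (14.6 kb).

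Of the 1332 non-transduced peaks, 417 overlapped a HOXA9 peak (31.3%, 95% interval 28.8 to 33.9). Conversely, 411 of the 620 HOXA9 peaks overlapped a non-transduced peak (66.3%, interval 62.4 to 70.0). At the level of merged regions, 398 of 1275 non-transduced regions also had a HOXA9 peak, and 201 of 599 HOXA9 regions had none in the non-transduced list. Non-transduced peaks with high scores were matched more often: 50.8% of the 333 with the highest scores (interval 45.2 to 56.2) against 22.5% of the 333 with the lowest (interval 18.1 to 27.4) overlapped a HOXA9 peak. In 385 one-to-one pairs the HOXA9 peak was narrower in 242, with a median width ratio of 0.921 (interval 0.890 to 0.965). Random placement of the HOXA9 peaks gave an overlap of 1.43% (central 95% of placements, 0.751 to 2.10) for the non-transduced list, and moving each by up to 1 Mb 5.26%.

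Of the full oncogene lists, PML-RARa matched the largest share of the non-transduced peaks, but the smallest share of its own peaks had a non-transduced partner. A PML-RARa peak overlapped 854 of 1332 non-transduced peaks (64.1%, interval 61.5 to 66.7), against 3.90% in random placements (2.85 to 5.11) and 12.8% when peaks were moved by up to 1 Mb. Of the 1772 PML-RARa peaks, 918 had no non-transduced partner, so 48.2% were shared (interval 45.8 to 50.6). These unpaired peaks were narrow, with a median width of 12.7 kb. Where 1 peak of each list formed a pair (741 pairs), the PML-RARa peak was slightly wider, with a median ratio of 1.03 (interval 1.01 to 1.05). Over all peaks the PML-RARa list was narrower, with a ratio of the median widths to the non-transduced list of 0.870 (interval 0.805 to 0.928), compared with 0.797 in MLL-AF9 (interval 0.736 to 0.857) and 0.944 in HOXA9 (interval 0.860 to 1.03). Of the 333 non-transduced peaks with the highest scores, 85.6% overlapped a PML-RARa peak (interval 81.3 to 89.2), and of the 333 with the lowest 45.3% (interval 39.9 to 50.9).

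The MLL-AF9 list overlapped 764 of 1332 non-transduced peaks (57.4%, interval 54.7 to 60.0), against 2.10 to 3.98% in the central 95% of random placements and 10.7% when peaks were moved by up to 1 Mb. Of its own 1408 peaks, 768 had a non-transduced partner (54.5%, interval 51.9 to 57.2). The 640 MLL-AF9 peaks without a partner had a median width of 11.5 kb. In 692 one-to-one pairs the MLL-AF9 peak was narrower in 419, with a median width ratio of 0.946 (interval 0.917 to 0.973).

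The share of non-transduced peaks matched in each list followed the length of that list. When the best 620 peaks of each list were compared, the share of non-transduced peaks with a partner was 41.6% in HOXA9 (interval 37.7 to 45.6), 43.4% in PML-RARa (interval 39.4 to 47.4) and 43.2% in MLL-AF9 (interval 39.3 to 47.2). These 3 shares lay within each other's intervals, so at equal list length they were close. All were scored on the same 620 non-transduced peaks, so separate intervals do not test the differences between the oncogenes, which were not tested. The best 620 peaks were the whole HOXA9 list, with a lowest score of 700, but only the higher-scoring part of the other lists. Their lowest scores were 940 in the non-transduced list, 1111 in PML-RARa and 1008 in MLL-AF9. At this length the 3 oncogene lists overlapped one another at 45.2 to 48.9% in the 6 ordered comparisons.

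**Figure D2:**
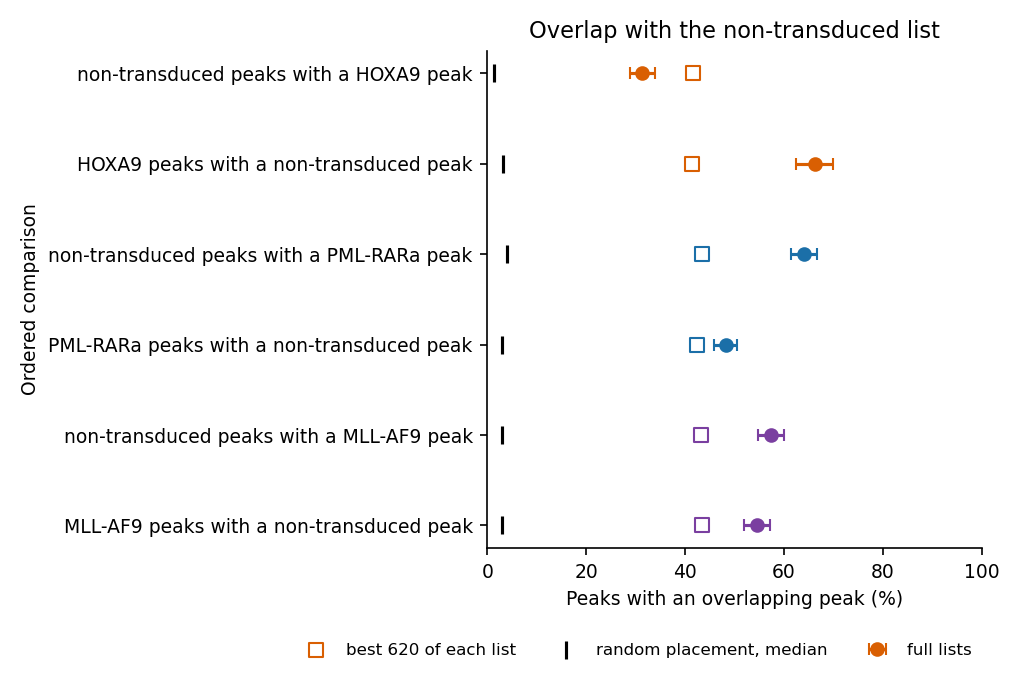
Percentage of peaks with an overlapping peak in the other list, for the non-transduced list against each oncogene list in both directions. Filled points are the full lists with exact 95% binomial intervals, open squares the best 620 peaks of each list, and ticks the median of 1000 random placements; with full lists the shares run from 31.3 to 66.3%, and at equal length from 41.5 to 43.4%.

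Merging all peaks gave 2575 regions, of which 309 (12.0%) had a peak in all 4 libraries and 1259 (48.9%) in 1 library only. Regions of 1 library only were most numerous in PML-RARa (580), followed by MLL-AF9 (324), the non-transduced library (309) and HOXA9 (46). A further 280 regions were present in all libraries but HOXA9, and without the HOXA9 library the regions common to the others numbered 589. Peaks in all 3 oncogene libraries but not in the non-transduced one marked 72 regions, and 267 when HOXA9 was left out. The non-transduced regions found in all 3 oncogene lists (309 of 1275) exceeded the 145 that lists overlapping them independently would give, and those found in none (309) exceeded the 137 of independent lists. Matching rose with the non-transduced score in all 3 lists, and independent lists within 10 classes of like score would give 187 and 175. All 3 comparisons share the single non-transduced library, which could not be split, and unchanged groups could not be simulated, so no excess here is a measure of a shared effect.

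**Figure D3:**
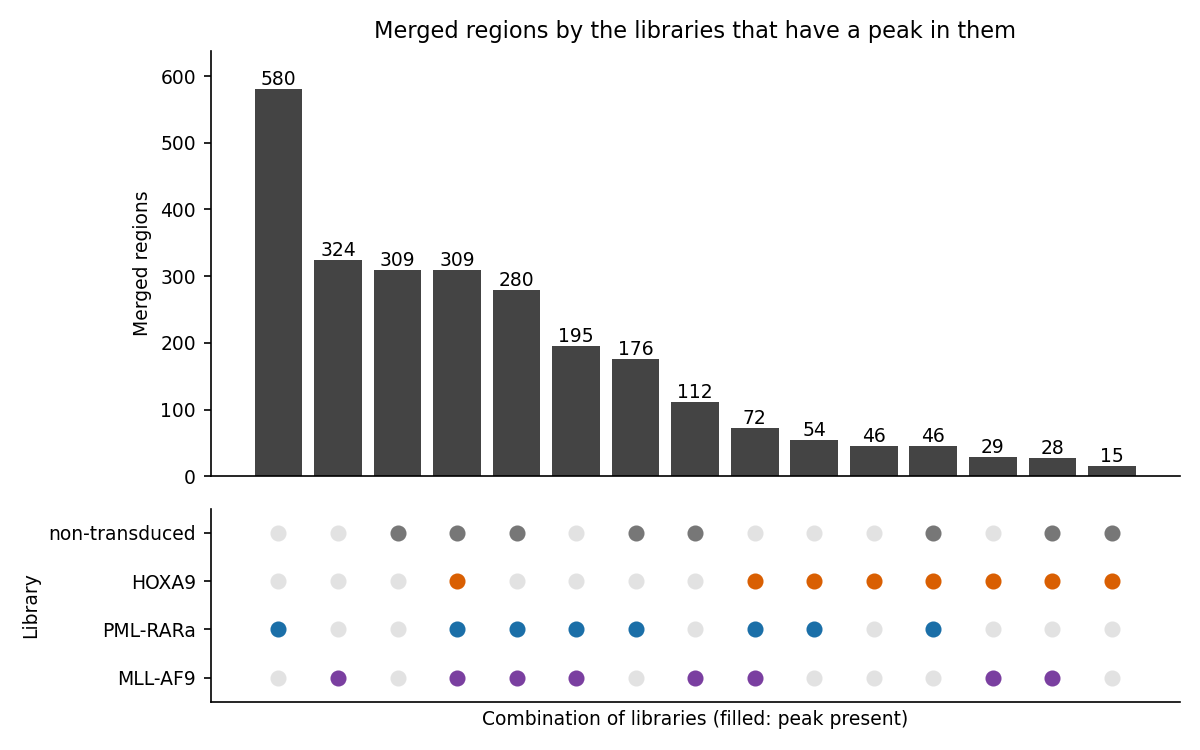
Number of merged regions (bars) for each combination of libraries with a peak in them (coloured dots below). Regions of PML-RARa alone are the most numerous (580), and 309 regions have a peak in all 4 libraries.

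Within each list, peaks matched in all other libraries were wider and had higher scores than peaks matched in none. Non-transduced peaks matched in no other library had a median score of 839, against 1022 for those matched in the 3 others. For HOXA9 peaks the median width was 11.6 kb with no match and 19.5 kb with a match in all others. For PML-RARa peaks the median width and score were 11.4 kb and 907 against 23.0 kb and 1262. For MLL-AF9 peaks they were 11.4 kb and 862.5 against 19.7 kb and 1118. In HOXA9 51.1% of the peaks were matched in all 3 other libraries, compared with 23.7% in the non-transduced library, 22.8% in MLL-AF9 and 319 of 1772 in PML-RARa. The numbers of such peaks were close (317 in HOXA9, 316 in the non-transduced library and 321 in MLL-AF9), so these shares differed through list length. Within the 309 regions of all 4 libraries the covered length was 9.70 Mb in the non-transduced library, 9.76 Mb in PML-RARa, 8.53 Mb in MLL-AF9 and 8.09 Mb in HOXA9.

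The region with the best mean score rank lay on chromosome 15 at 88954187 to 89041315. It held a peak of 66.4 kb in the non-transduced library, 70.2 kb in HOXA9, 87.1 kb in PML-RARa and 64.2 kb in MLL-AF9, and it had the highest score of the PML-RARa list (2763). A region on chromosome 11 at 85624043 to 85667244 had the highest score of the HOXA9 list (1736). The region with the highest score in the non-transduced list (2107) was on chromosome 19 at 45280500 to 45360024, and the one with the highest score in MLL-AF9 (2246) on chromosome 7 at 19626349 to 19704233; both had peaks in all 4 libraries. A region on chromosome 15 at 98587466 to 98642154 was covered over 43.7 kb in the non-transduced library, 36.5 kb in HOXA9, 54.7 kb in PML-RARa and 11.1 kb in MLL-AF9. On chromosome 14, the region at 121844332 to 121882200 was covered over 18.4 kb in the non-transduced library, 32.9 kb in HOXA9, 37.8 kb in PML-RARa and 31.0 kb in MLL-AF9.

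A region on chromosome 6 at 52141970 to 52210289 was covered almost completely by 1 peak in the non-transduced library (68.3 kb), in HOXA9 (64.5 kb) and in PML-RARa (68.2 kb). The MLL-AF9 peak there was 26.4 kb long and began at position 52183835. The right ends of the 4 peaks lay within 53 bp of each other, and the left ends spread over 41865 bp.

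**Figure D4:**
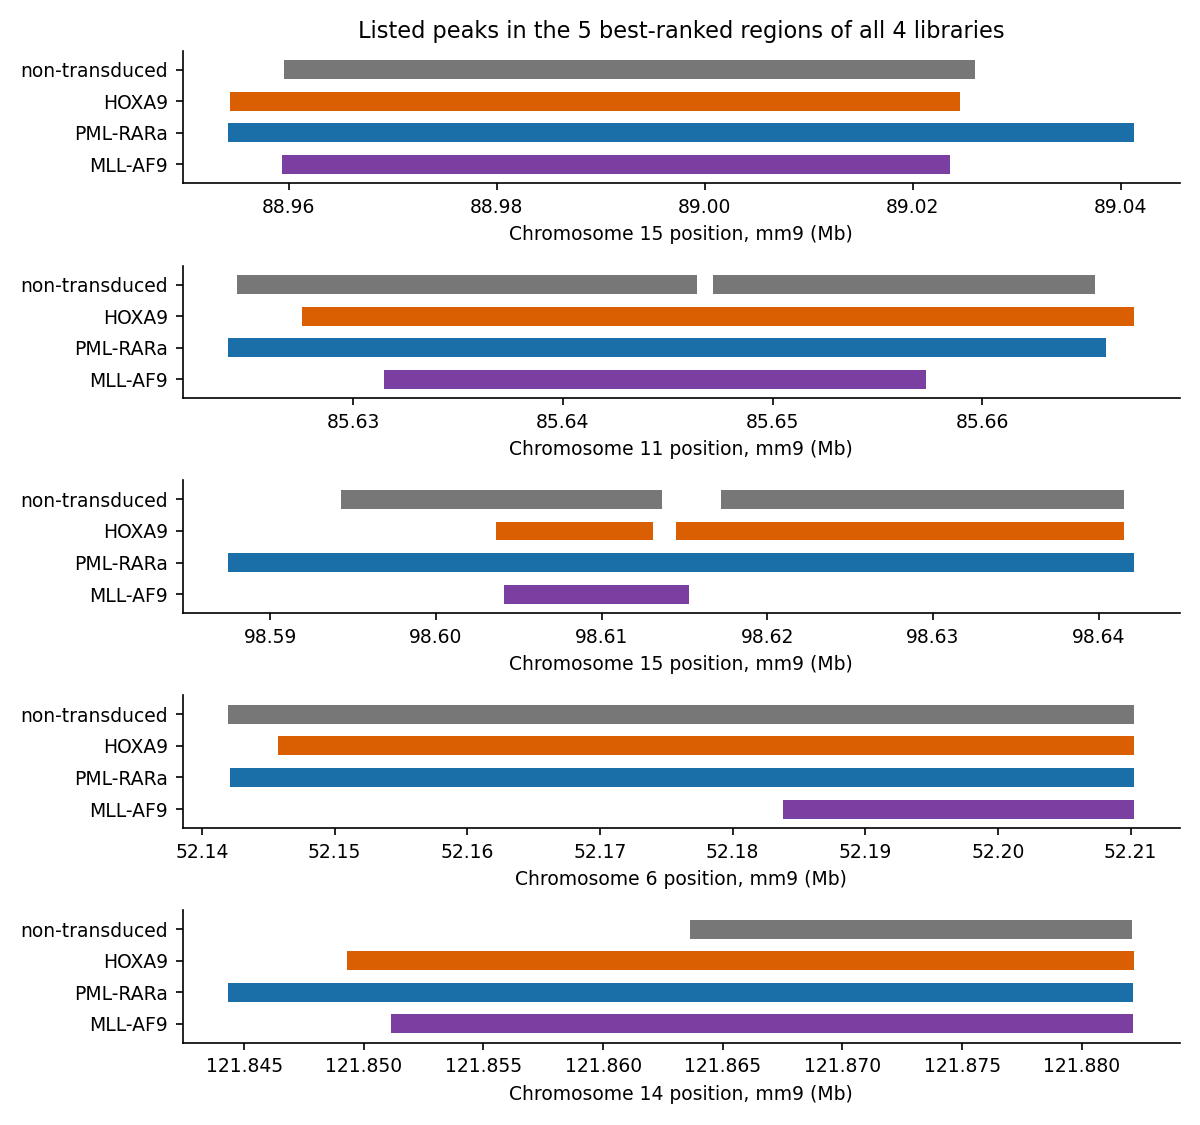
Listed peaks of each library (bars, to scale, mm9 position in Mb) in the 5 regions of all 4 libraries with the best mean score rank. On chromosome 6 the MLL-AF9 peak covers 26.4 kb at the right of a region that the non-transduced peak covers over 68.3 kb.

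Among the 72 regions with a peak in all 3 oncogene libraries and none in the non-transduced list, the best-ranked was on chromosome 3 at 88296623 to 88349796. It was covered over 53.2 kb in PML-RARa, 27.8 kb in MLL-AF9 and 8.82 kb in HOXA9. The next were on chromosome 13 at 31884656 to 31915437 and on chromosome 6 at 96941149 to 96998534, where the HOXA9 peaks spanned 30.8 kb and 44.0 kb. A region on chromosome 11 at 69038234 to 69055245 had a HOXA9 score of 1389, and a region on chromosome 4 at 148924008 to 148964929 was covered over 40.5 kb in HOXA9, 20.3 kb in MLL-AF9 and 6.60 kb in PML-RARa. Absence from the non-transduced list means that no peak with a listed score was there, not that the mark was absent.

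Of the 309 regions listed in the non-transduced library alone, the highest score (1628) was on chromosome 2 at 156599367 to 156615407. On chromosome 6, a peak of 79.5 kb at 125260686 to 125340191 (score 1329) and one of 1.06 kb at 125367746 to 125368803 (score 1522) lay near each other, and a further one was at 87529444 to 87541821 (score 1452). A peak of 53.7 kb on chromosome 9 at 42940002 to 42993681 had a score of 1306.

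Regions of a single oncogene library included peaks near the top of their list in PML-RARa and MLL-AF9. In PML-RARa alone, the highest scores were 2443 on chromosome 17 at 36364104 to 36372105, 1825 on chromosome 2 at 118795126 to 118810043 and 1800 on chromosome 17 at 39980015 to 39983632. Further PML-RARa regions were on chromosome 11 at 120388850 to 120407036 (score 1784) and chromosome 13 at 113767480 to 113793457 (score 1755). In MLL-AF9 alone, a peak on chromosome 4 at 135736083 to 135752501 had a score of 1937 and one on chromosome 15 at 74336666 to 74358364 a score of 1930. The widest peak of the MLL-AF9 list, 131 kb on chromosome 5 at 125496784 to 125628069 (score 1537), was also in that library alone. The MLL-AF9 regions on chromosome 11 at 83216451 to 83228082 and at 97298985 to 97316386 had scores of 1505 and 1451. The best region of HOXA9 alone, on chromosome 16 at 90827351 to 90840574, had a score of 1197, followed by 1118 on chromosome 7 at 35431912 to 35445613.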

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

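All differences in this part compare single libraries and were not tested; the tests of other peaks in the MLL-AF9 list and of all numbered HOXA9 calls, and the count of peaks without a missing HOXA9 number, were chosen after the results were seen. The oncogene libraries lay on opposite sides of the non-transduced one. The number of listed peaks differed from the non-transduced list by -712 in HOXA9, by 440 in PML-RARa and by 76 in MLL-AF9. The listed share of the numbered peaks was unequal: 75.4% in the non-transduced list, 66.8% in HOXA9, 83.4% in PML-RARa and 77.8% in MLL-AF9. With unlisted calls included, the ratios to the non-transduced numbering were 0.525, 1.20 and 1.02. The MLL-AF9 numbering of 1810 (exact 95% Poisson interval 1728 to 1895) was then close to the non-transduced 1766. The covered length differed from the non-transduced list by -18.0 Mb in HOXA9, by 4.29 Mb in PML-RARa and by -4.42 Mb in MLL-AF9.

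The short HOXA9 list was weighed against a score filter, which is one reading of the gaps in the peak numbers, and against a lower depth or enrichment of that library. Such a filter, or any other removal of numbered peaks, is argued against as the reason for the shorter list: with unlisted calls included the HOXA9 numbering ran to 928 (exact 95% Poisson interval 869 to 990) and the non-transduced one to 1766, with the last listed peaks of both in 1 region of chromosome X. Of the 915 non-transduced peaks without a HOXA9 partner, 329 lay where no HOXA9 number was missing, so no numbered call was left out there. Removal stays open only for the other 586 (64.0%), against 308 missing numbers in the whole list. This share lay between the bounds fixed beforehand, so the planned test was undecided. No number was missing at 271 of 478 unmatched non-transduced peaks for PML-RARa and 261 of 568 for MLL-AF9, so this count does not single out HOXA9. A lower depth or enrichment may contribute, as unmatched non-transduced peaks had lower scores than matched ones (area under the curve 0.652, 95% interval 0.618 to 0.685). The same area was 0.683 for PML-RARa and 0.658 for MLL-AF9, whose lists were not shorter, so this test does not single out HOXA9, and an effect of HOXA9 itself remains open as untested with 1 library.

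The narrower MLL-AF9 peaks were weighed against the splitting of wide domains, a lower enrichment and a different set of peaks. Splitting into listed peaks is argued against as the whole explanation, since in one-to-one pairs the median width ratio was still 0.946, below 1 by more than its interval. More than 1 MLL-AF9 peak lay on 27 non-transduced peaks, and 24 MLL-AF9 peaks lay over more than 1 non-transduced peak. Splitting into unlisted pieces stays open, since 402 MLL-AF9 numbers were missing and such pieces would leave a narrow pair. A lower enrichment stays open: the scores of the same pairs had a median ratio of 1.05 and were meant to decide it, but scores of separately called lists have no common scale, so that bound was wrong and the value decides nothing. A part played by peaks listed in 1 library and not the other also stays open. The ratio of the median widths was 0.797 for the whole lists (95% bootstrap interval 0.736 to 0.857) and 0.870 for the pairs (interval 0.817 to 0.919). These intervals overlap, but the pairs are part of the whole lists, so the overlap cannot decide it. Peaks without a partner were narrower than paired ones in MLL-AF9 (median 11.5 against 17.6 kb) and in the non-transduced list (15.9 against 20.2 kb). An effect of MLL-AF9 on the width stays open as untested, and the pairs do not single it out, since HOXA9 pairs had a median ratio of 0.921 with 62.9% narrower, against 60.5% narrower in MLL-AF9.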

How the results depend on the processing

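The ratios of covered length to the non-transduced list kept their side of 1 and stayed within 1.5 times under each alternative tried (the upper 75% or 50% by score, and merging within 1000 bp). Merging within 1000 bp or counting peaks within 1000 bp as shared left each overlap share within its 95% interval and each peak and region count within 1.5 times its value. Of the overlaps between oncogene lists, the random placements and the expected numbers of shared regions, 24 values moved by more than their interval and 16 did not, or stayed within 1.5 times for the expected numbers; with classes of like score and covered length, added later, these were 193 in all 3 oncogene lists and 180 in none. With the upper 50% by score, the lists held by construction 666 (non-transduced), 310 (HOXA9), 886 (PML-RARa) and 704 (MLL-AF9) peaks. The shares of non-transduced peaks matched in HOXA9, PML-RARa and MLL-AF9 were then 25.1%, 54.4% and 46.1%, and the shares of HOXA9, PML-RARa and MLL-AF9 peaks matched in the non-transduced list 52.9%, 40.7% and 43.8%. Requiring an overlap of at least 50% of the peak, a stricter rule by construction, gave 26.5%, 58.2% and 49.6%, and 62.3%, 42.9% and 51.1%, in the same order. With the best 620 peaks of each list they were 41.6%, 43.4% and 43.2%, and 41.5%, 42.4% and 43.4%. The differences between the oncogenes seen with full lists were then smaller than the intervals. This setting changes the list length and also keeps only the higher-scoring non-transduced peaks, and the effects of the changes cannot be told apart. The merged regions numbered 1363 at equal length and 1441 with the upper 50%, those of all 4 libraries 118 and 99, and those of the non-transduced library alone 199 at equal length, with fewer peaks in each list. Without HOXA9, a library doubted for its short list and left out after seeing the data, the regions common to all others were 589 and those in both other oncogene libraries but not in the non-transduced one 267, since 1 list fewer has to hold them. Alternatives for promoter windows, gene bodies and gene groups were not run, because genes were not assigned to mm9 positions. Placements that moved each peak by up to 1 Mb, also added later, gave a higher chance overlap, and in 12 of 12 ordered comparisons the observed share exceeded the highest of the random ones. The unknown depth limits every comparison of list length.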

Other observations

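The region rule for this part, and so the choice of the chromosome 6 region, was made after the data were seen; the tests of the score filter, there and on chromosome X, were written before their results were seen. Of the 309 regions of all 4 libraries, 51 were covered over at least 50 kb in the non-transduced library. Among these, MLL-AF9 covered under 50% of the non-transduced extent in 9, HOXA9 in 17 and PML-RARa in 8. Choosing regions by their non-transduced extent favours shorter extents in the other libraries. In reverse, the non-transduced library covered under 50% of the oncogene extent in 4 of 40 regions of at least 50 kb in MLL-AF9, in 2 of 35 in HOXA9 and in 4 of 48 in PML-RARa. Among these 51, regions where 1 oncogene library fell under 50% while both others reached at least 80% numbered 3 for HOXA9, 0 for PML-RARa and 1 for MLL-AF9. The HOXA9 regions were on chromosome 1 at 75433283 to 75509738 (31.8% of the non-transduced extent), chromosome 7 at 86628546 to 86696517 (37.9%) and chromosome 15 at 82737469 to 82808198 (42.2%). Beside the listed HOXA9 peak of these regions 3, 1 and 1 HOXA9 numbers were missing, so an unlisted call is not excluded there as it is for the MLL-AF9 region. The MLL-AF9 region was that on chromosome 6 at 52141970 to 52210289 (38.7%, against 94.6% in HOXA9 and 99.8% in PML-RARa). Regions covered over less than 50 kb in the non-transduced library showed the same pattern for each oncogene library. Examples for MLL-AF9 began on chromosome 15 at 98587466 (ratio to the non-transduced extent 0.254) and on chromosome 7 at 134082754 (0.364). In the chromosome 15 region, 27.1 kb of the 36.5 kb HOXA9 extent came from a peak with a score of 700, the lowest of any list. Without that peak HOXA9 would be short there too. One for HOXA9 began on chromosome 9 at 121538601 (0.251), and one for PML-RARa on chromosome 11 at 95420950 (0.495). Missing peak numbers were not examined at these narrower regions, so unlisted calls are not excluded there.

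A hypothesis is that MLL-AF9 cells may have had less of the mark over the left part of this chromosome 6 domain, up to position 52183835, while keeping it on the right. The score filter predicted that an MLL-AF9 peak number would be missing between the listed peak and the one before it, which ended at 51147329. With 0 numbers missing there, the score filter cannot have removed an MLL-AF9 call from the left part. A lower enrichment of the whole library remains open. So does chance, since the region came from a search of 51 regions in each of the 3 oncogene libraries, with limits chosen after the data were seen. A replicate would be needed, and also cells transduced without an oncogene, which were not among the samples. By their listed peaks, narrower regions were also short in MLL-AF9 alone, so this domain was not the only one with this pattern.

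Chromosome X held 2 peaks in the non-transduced library, 2 in HOXA9, 6 in PML-RARa and 6 in MLL-AF9, while the autosome with the fewest peaks held 29, 14, 39 and 29. The score filter was tested as a reason and cannot account for this before the last listed X peak in any of the 4 libraries. Even if every missing number that could precede the last listed X peak lay on X, it would have held at most 4, 2, 7 and 7 peaks up to there. Of 11 merged X regions none had a peak in all 4 libraries; those at 90519874 to 90553205 (the 3 oncogene libraries) and 137529289 to 137534051 (all but PML-RARa) had peaks in 3. On chromosome 3, HOXA9 had 31 of its 620 peaks (exact 95% interval 3.42 to 7.02%) and the non-transduced library 35 of 1332 (2.63%, interval 1.84 to 3.64). The HOXA9 peak number there was 0.886 of the non-transduced one, against 0.465 for the whole lists and 0.323 on chromosome 1. PML-RARa (1.8 against 1.33 for the whole lists) and MLL-AF9 (1.37 against 1.06) were raised there too. All 3 ratios share the non-transduced count of 35, so the pattern was not particular to HOXA9. On chromosome 13 PML-RARa had 71 peaks against 32, a ratio of 2.22, the highest of any autosome in any of the 3 oncogene libraries. Its whole-list ratio was 1.33. HOXA9 (0.656 against 0.465 for the whole lists) and MLL-AF9 (1.22 against 1.06) were also raised there, with the same non-transduced count. In all, 20 chromosomes were looked at and none of these differences was tested.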
